A study of Oryza sativa with 2 samples.

How the data were processed

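The study used rice (Oryza sativa) seedlings grown in a growth chamber on MS medium, a standard plant culture medium, for 7 days. Whole seedlings were exposed to carbon ion beams from an accelerator, for 2 h 35 min per the labels, and untreated seedlings served as the control. Per the labels' protocols, total RNA was taken with TRIZOL and labelled with an Agilent linear amplification kit. Per the series' design text, the arrays were an Agilent rice oligonucleotide design, read on a GenePix scanner with its own image software. The labels name 2 arrays, each with control RNA as channel 1 and irradiated RNA as channel 2. On the first array the irradiated RNA carried Cy5 and the control Cy3, and on the other array the dyes were swapped. Both labels give the same replicate number, so the arrays were treated as a dye swap of the same pair of extracts and counted as 1 replicate per group.

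The deposited values are log10 ratios of the 2 channels of an array, 22575 per array. 1 value is missing, which left 22574 probes. The unit was worked out from the values, because the file has no header that names it. The simplest fraction within the 9 printed decimals had terms with medians of 143 and 163 on the first array and 205 and 166 on the swapped array. After a small random change of each value the same search gave medians of 27668 and 26058 on the first array and 32736 and 22058 on the swapped array. The deposited values are therefore read as log10 ratios of whole-number spot intensities. The design text names GeneSpring version 4 for normalization, but the columns had medians of 0.051 and 0.20 log10 units and followed spot intensity, so no normalization was taken to have been done in them. Background handling and the numerator of the ratio are not given in the sources used here.

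The recovered terms gave a rough intensity for each spot, the geometric mean of the channels. A fraction that had been reduced lost its common factor, and the most likely factor up to 59 was put back with the help of the other array. In simulated arrays 69.7% of 22574 probes came within 0.3 log10 units of their true intensity on each array, so intensity ranks probes only coarsely. Each array was normalized by loess of the log ratio on this intensity (span 0.3, 3 robustness iterations), and the residuals were taken to log2. Loess was not in the plan, which assumed the values could be used as deposited, and was added after the data were seen. The fitted trend ran from -0.39 to 0.48 log10 units on the first array and from -0.23 to 0.69 on the swapped array.

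The direction was settled only in part. The labels make irradiated RNA channel 2 on both arrays, so ratios of channel 2 over channel 1 would be irradiated over control in both columns. The plan, written before the data were examined, took that reading unless the columns correlated below 0 over all probes, and they correlated at r = 0.67 over 22574 probes. That rule had assumed normalized values. After loess the columns still correlated at 0.25 over all probes, and between 0.088 and 0.54 in deciles 1 to 8 by intensity. The planned rule would therefore have kept its reading after normalization too. They correlated at -0.62 in the second brightest decile and at -0.44 in the brightest, where the dye trend and noise are smallest. On those 2 deciles alone, both columns were read as the same dye over the other and the swapped array was turned. This departs from the plan and was decided after the data were seen. Neither label nor file says which dye is the numerator. Cy5 over Cy3, the usual order for these scanners, was used, and every direction given is therefore likely and not certain.

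Genes were named from the platform annotation, which lists 17860 probes by number, 17839 of them with 1 gene and 21 with several. It leaves 4715 probes unlisted, which are unnamed here. All 17839 were matched by gene number to the RefSeq gene table of assembly ASM3414082v1, used for names only, and 2410 probes of 2109 genes had a name beyond a locus number. The annotation's numbers did not pair with the row numbers as listed. 202 spots above the median intensity lay at least 4-fold below their array's trend on both arrays, the mark of spots that follow the dye and not the sample. As listed, 15.8% of them were unlisted, against 21.0% of all probes. Each of 134 ways to number a rectangular grid was scored. In the numbering that runs down the columns of a grid of 105 rows and 215 columns from the opposite corner, 98.5% of these spots were unlisted, and no other numbering reached over 34.7%. The same numbering gave a median intensity of 16623 for photosynthesis probes, against 126 as listed and at most 782 in the others. It also gave a correlation of intensity of 0.21 over 2227 probe pairs of the same gene, where the others lay between -0.054 and 0.046. If both columns are the same dye over the other, none of these scores uses the difference between irradiated and control. The first score rests on that reading, since with both columns as irradiated over control these spots would be lower in irradiated seedlings. The intensity scores do not use that difference under either reading. This numbering was used throughout, was chosen after the data were seen, and every gene name rests on it.

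Because there is 1 replicate per group, no test was made and no p-value is given. A probe counted as higher or lower when its ratio was at least 2-fold, in the same direction, on both arrays. The mean of the arrays is the reported ratio. The part that follows the dye holds array noise and also dye bias, which cancels in that mean, so it measures technical error only roughly. Probe values of the swapped array were also shuffled 100 times within deciles of intensity, to count calls expected from unrelated arrays. 21 gene lists were fixed before the data were examined, as patterns on gene descriptions or symbols. The gene annotation used held no descriptions for rice, so the patterns could be matched to gene names only, which departs from the plan. Afterwards 3 names that matched the root list by spelling alone were removed. Each list's median was placed among 10000 random lists of the same number of probes drawn from probes with a gene name, and again among lists matched on intensity. Lists with under 5 genes got no percentile. Percentiles under 2.5 or over 97.5 were called low or high, as a description of these extracts. The rule for named genes took the 12 highest and 12 lowest named genes by the smaller of the 2 ratios, at 2-fold or more on both arrays, and the highest and lowest member of each list at 1.5-fold or more on both.

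The steps were tested on simulated arrays that carried the real trends and noise and 200 changed probes in the 5 brighter deciles. Of 50 probes changed 2-fold, 24% were called, of 50 changed 4-fold, 86%, and of 50 changed 8-fold, 100%. Of 11087 unchanged probes in the brighter deciles 76 were called, and of 11287 in the dimmer deciles 129. Of 300 unchanged lists, drawn from independent random values and not from these arrays, 6.67% fell outside percentiles 2.5 to 97.5. On that basis about 1 of the 19 lists could be called by chance. Probes of a real list can vary together, so the number for the real lists can differ. All 10 simulated grid numberings were found, but in separate random values, not in these arrays. There every spot that follows the dye was placed at an unlisted probe, so the true numbering scored highest by design. This result therefore cannot speak for the numbering recovered from the real arrays. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Alternatives planned were other thresholds, median centring with or without scaling, each array alone, counts per gene and matched random lists. Alternatives added after the data were seen were the as-deposited reading, the opposite numerator, other loess settings, bright probes alone, lists per gene or matched on intensity, and the numbering as listed. An alternative without values at a floor or ceiling shared by over 10 probes removed nothing, since the lowest and highest value of each array belonged to 1 probe.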

Results

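Gene expression in whole 7-day-old rice seedlings exposed to carbon ion beams, a densely ionizing form of radiation, was set against that in untreated seedlings. There were 2 two-channel arrays. Each compared the same irradiated extract with the same control extract, with the dyes swapped between arrays, so there was 1 replicate per group. Ratios of irradiated over control were measured for 22574 probes on both arrays, of which 17839 had 1 gene and 2410 had a gene with a name. No difference given here has a replicate check, and the number of arrays limits the precision. All ratios are log2 of irradiated over control after normalization, given as the mean of both arrays unless each is named. Their direction is likely only, since it rests on reading the deposited values as Cy5 over Cy3, and gene names rest on a probe numbering recovered from the values.

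The comparison asks which transcripts differ between seedlings exposed to the beam and controls. Among named genes the highest in irradiated seedlings was EL2, an elicitor-responsive gene that encodes an inhibitor of cyclin-dependent kinases, at 4.86 on the first array and 4.73 on the swapped array, a mean of 27.8-fold. When intensities were used without restored common factors its mean was 5.67. It was followed by SAP17, a stress-associated zinc-finger protein, with a mean of 4.05, by the mitogen-activated protein kinase MAPK5 with 3.98, and by the calmodulin-like protein CML31 with 3.75. Transcripts of WRKY24 and WRKY71, of the WRKY family of transcription factors, had means of 3.75 and 3.28. Far fewer transcripts were lower, and those that were differed less, with the means of named genes that were lower on both arrays between 2.22-fold for CSLA5 and 2.53-fold for the kinase CIPK7, of which another, brighter probe stood at -0.14.

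In all, 423 probes were at least 2-fold higher on both arrays and 68 were at least 2-fold lower, so 86.2% of these probes were higher. They stood for 388 genes that were higher and 59 that were lower. At 3-fold the counts were 187 higher and 7 lower, and at 4-fold 101 and 2. If the deposited values were Cy3 over Cy5, the 2-fold counts would be 68 higher and 423 lower. The other named genes among the 12 highest were the transcription factors BHLH148 with a mean of 3.04, NAC067 with 2.96, or 3.63 without restored common factors, MYB4 with 3.02 and HSF23, a class B heat shock factor, with 2.69. The set also held the Dicer-like RNA-processing enzyme DCL2A with 2.64 and the lipoxygenase LOX9 with 3.01. Another probe of BHLH148 stood at -0.08, so the probes of that gene disagree, and another probe of DCL2A stood at 0.91. The highest genes without a name were LOC4331157 at 5.51 and LOC4333197 at 4.88. The lowest were LOC4333827 at -2.28 and LOC4337946 at -2.21.

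**Figure D1:**
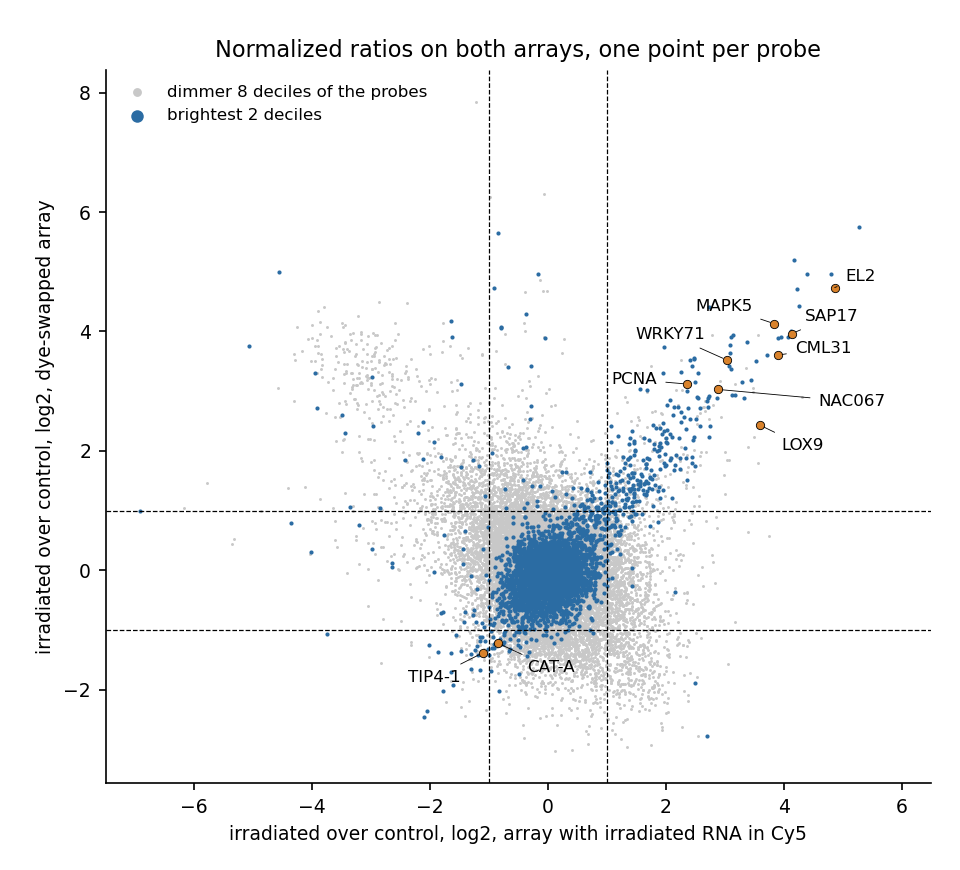
Normalized log2 ratios of irradiated over control for each of 22574 probes, with the array that carried irradiated RNA in Cy5 on the horizontal axis and the dye-swapped array on the vertical axis. Blue points are the brightest 2 deciles of the probes, grey points the others, dashed lines mark 2-fold, and orange points are named genes such as EL2 at 4.86 and 4.73; the blue points extend along the diagonal to the upper right, and the grey cloud at the upper left holds spots that follow the dye.

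The list of jasmonate and ethylene synthesis and signalling genes had the highest median among the fixed lists with at least 5 genes. Of its 7 probes past 2-fold, 6 were lipoxygenase, allene oxide synthase or JAZ probes. Of 43 probes for 40 genes, 7 were at least 2-fold higher on both arrays and 0 were lower, and the list median of 0.36 lay at percentile 100 of random lists, with or without matching on intensity. The members that were higher included the lipoxygenases LOX9 and LOX5, with LOX5 at 2.17. Lipoxygenases serve jasmonate synthesis and other pathways, and the name of LOX5 does not tell which. The allene oxide synthase AOS1, which acts in jasmonate synthesis, stood at 1.58, or 2.33 without restored common factors. The JAZ repressors JAZ11, JAZ12 and JAZ10, which jasmonate signalling removes, stood at 2.39, 2.05 and 1.99. ACS2, an enzyme of ethylene synthesis, stood at 2.03, but the other 8 ethylene probes lay between -0.65 for a dim probe of the receptor ETR3 and 0.34 for the receptor ERS1. On the swapped array alone the median of this list was 0.17, at percentile 96.0, which is no longer high. With the annotation's probe numbers taken as listed it was -0.030, and 0 of the 19 lists were then high or low. Under Cy3 over Cy5 every list median would change sign. This list would then have the lowest median, and the high and low lists would exchange.

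The list of WRKY, NAC, AP2/ERF and MYB transcription factors was also high, with 9 of 34 probes at least 2-fold higher and 0 lower. Of these 9 probes 3 were WRKY, 5 NAC and 1 MYB, and 0 were AP2/ERF, where values ran from 0.72 for a dim probe of ERF78 to -0.17 for a dim probe of AP22. AP25, at -0.44, matched the list by its spelling and likely encodes a protease. The list's median was 0.21, at percentile 99.5, or 99.4 when matched on intensity. Besides WRKY24, WRKY71, NAC067 and MYB4, the higher members were WRKY76 at 2.36 and the NAC factors NAC068 at 2.28, NAC45 at 2.21, NAC071 at 1.53 and NAC074 at 1.47. Another, dim probe of NAC071 stood at 0.05. The lowest member past 1.5-fold was MYBS1, a MYB factor of sugar-regulated amylase genes, at -0.88. The list fixed for abscisic acid and dehydration held protein phosphatases 2C apart from 5 probes, and had a median of 0.20 over 56 probes, at percentile 99.95, or 99.9 when matched on intensity. Only 1 of its probes was at least 2-fold higher, OsPP2C27 at 1.59, and 0 were lower. The 5 other probes, of dehydration and salt marker genes, stood at 0.26 for RAB16C, 0.24 for RAB16D, 0.15 for RAB16B, 0.06 for Dhn1 and -0.54 for salT. The phosphatase OsPP2C75 was the lowest at -1.29 and -0.72 on the arrays, while another probe of that gene stood at 0.26. On the swapped array alone this list's median was 0.07, at percentile 83.4.

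Calcium and MAP kinase signalling genes did not stand apart by their list median, although MAPK5 and CML31 were among the highest named genes. Of 83 probes, 5 were at least 2-fold higher and 1 was lower, where of all 2410 named probes 66 were higher and 8 lower. At 1.5-fold 10 were higher and 4 lower. The median of -0.0024 lay at percentile 46.5, or at 90.9 with median centring, which is not high. Besides MAPK5 and CML31, the higher members were CML16 at 1.41, the kinase CIPK23 at 1.41 and MAPKK1 at 1.26. Another, brighter probe of CIPK23 stood at -0.18. CIPK7, a kinase of the family that acts with calcineurin B-like calcium sensors, was the lower one at -1.34, while its other, brighter probe at -0.14 disagrees.

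Named genes of DNA repair and the DNA damage response did not stand apart, but 15 of their 24 probes were among the dimmer 5 deciles, where calls cannot be set apart from technical error. The same held for 31 of the 50 cell cycle probes, 12 of the 15 pathogenesis-related, 15 of the 23 phenylpropanoid, 22 of the 30 P450, 10 of the 12 seed storage and 33 of the 62 cell wall probes. None of the 24 DNA repair probes, for 17 genes, reached even 1.5-fold on both arrays (0 higher and 0 lower), with a median of 0.03 at percentile 61.8. Among 50 cell cycle and replication probes 3 were at least 2-fold higher and 0 lower, and the median was -0.02 at percentile 37.3. PCNA, the sliding clamp of DNA polymerase, was the highest at 2.36 on the first array and 3.12 on the swapped array, a mean of 2.74, or 2.11 without restored common factors. The others were the cyclin-dependent kinases CDKG-1 at 1.24 and CDC2-2 at 1.13. The histone list held 0 named genes.

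Antioxidant enzymes held 1 probe of 63 that was at least 2-fold higher, the alternative oxidase AOX1 of the mitochondrial electron chain at 1.55 from a dim probe, and 0 that were lower, with a median of 0.03 at percentile 72.1. The catalase CAT-A, which breaks down hydrogen peroxide, was the lowest member at -0.85 and -1.22 on the arrays. Glutathione S-transferases had a median of 0.12 over 8 probes at percentile 78.8, with GSTU6 the highest at 1.02 and none past 2-fold on both arrays. Of the 2 secretory peroxidases, LOC4344277 stood at 1.11, but at 0.24 when intensities were used without restored common factors. The pathogenesis-related list, which was made up of chitinases apart from PBZ1, had a median of 0.11 over 15 probes at percentile 83.2, from a chitinase at 0.85 to PBZ1, a probenazole-inducible defence protein, at -1.25. Phenylpropanoid and phytoalexin genes had a median of 0.08 over 23 probes at percentile 82.1, and the highest was the phenylalanine ammonia-lyase PAL06 with 1.72 and 0.74 on the arrays. None of these last 2 lists had a probe past 2-fold on both arrays.

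Heat shock proteins and chaperones held 2 of 38 probes at least 2-fold higher, HSF23 and the heat shock factor HSF09 at 1.34, and 0 lower, with a median of 0.07 at percentile 83.2. The chaperone HSP101 was the lowest at -0.87. Of 30 cytochrome P450 probes 2 were higher and 0 lower, with a median of -0.03 at percentile 35.3. These were AOS1, which is itself a P450, and CYP707A5, of the family that breaks down abscisic acid, at 1.52. The lowest was CYP88A5, an enzyme of gibberellin synthesis, at -0.84. Of 29 proteasome and ubiquitin probes 2 were higher, the polyubiquitin UBQ3 at 1.91 and the proteasome subunit PBC1 at 1.26, and 0 lower, with a median of 0.08 at percentile 84.5.

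Cell wall growth genes, such as expansins and cellulose synthase-like proteins, were slightly lower as a list, with a median of -0.13 over 62 probes, 33 of them dim, at percentile 1.88, or 2.58 when matched on intensity, which is no longer low. On the swapped array alone the median was -0.07, at percentile 29.9. Only CSLA5, at -1.15, was at least 2-fold lower, and 0 were higher. Root-enriched transport genes had a median of -0.13 over 64 probes at percentile 1.43, but 0.04 on the swapped array alone, where the direction turned, and with median centring in place of loess it lay at percentile 7.66, or 3.47 with scaling as well, and without restored common factors at 3.23. Among them 1 probe, of the phosphate transporter PHT1-8, was higher at 2.14, while another probe of PHT1-8 stood at -0.03, and 1 probe was lower, the aquaporin TIP4-1 at -1.25. Photosynthesis probes had a median of -0.05 over 6 probes at percentile 37.8, ribosomal proteins one of 0.04 over 22 probes at percentile 65.0, and seed storage and reserve genes one of -0.14 over 12 probes at percentile 14.8, all with 0 probes past 2-fold on both arrays. Housekeeping references had a median of -0.01 over 19 probes at percentile 41.6, and 1 of them, the actin ACT7, was higher at 1.32.

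**Figure D2:**
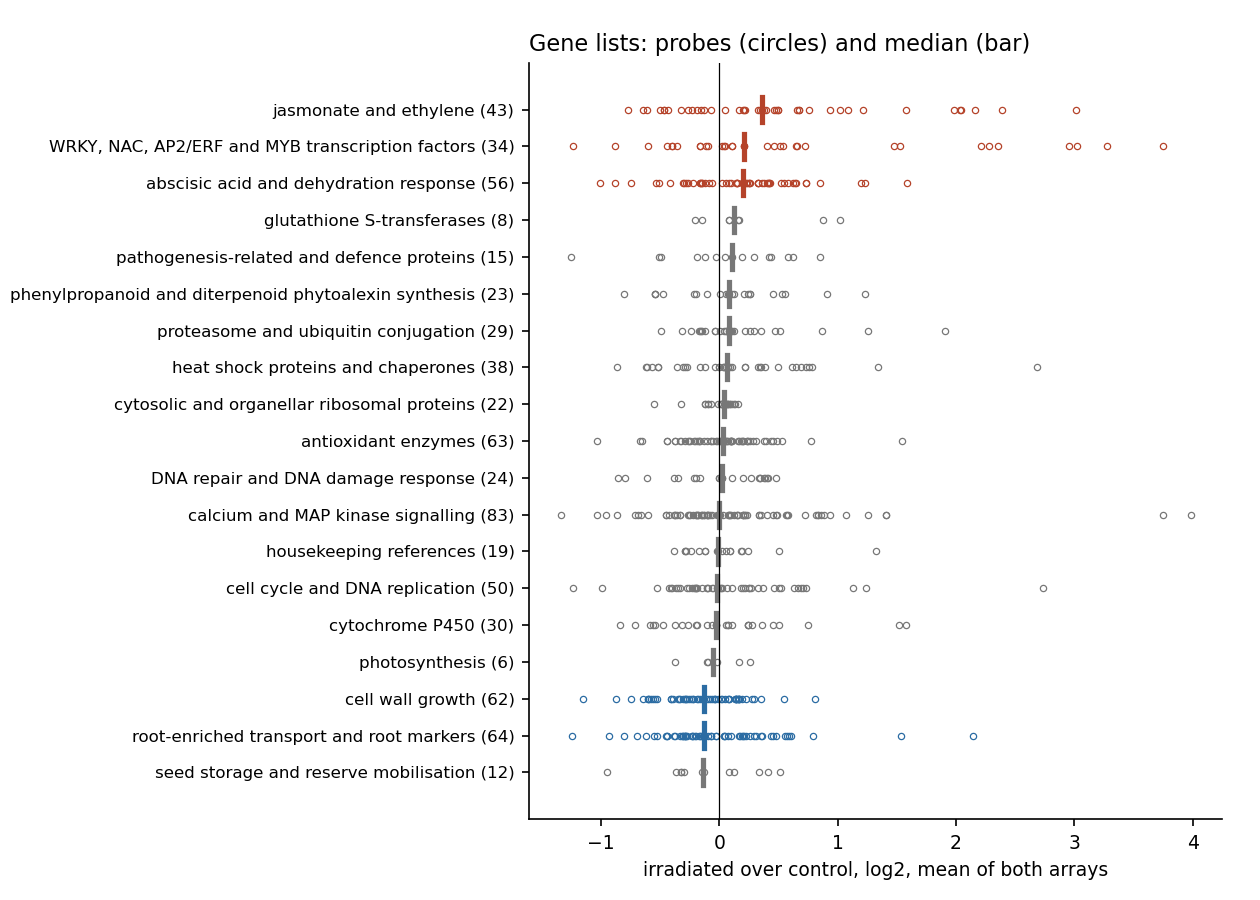
Log2 ratios of irradiated over control, as the mean of both arrays, for the probes of the 19 gene lists that had at least 5 genes, with the number of probes in parentheses. Circles are probes and bars are list medians, red where the median lies above percentile 97.5 of random lists and blue where it lies below percentile 2.5. The jasmonate and ethylene median of 0.36 is the highest when values are read as Cy5 over Cy3. Under Cy3 over Cy5 it would be the lowest, and red and blue would exchange.

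Only 8 named genes were at least 2-fold lower on both arrays. Besides the TCP transcription factor PCF7 at -1.30, CIPK7, TIP4-1 and CSLA5, they were the CCCH zinc-finger proteins OsC3H37 and OsC3H54 at -1.30 and -1.32, the bHLH factor BHLH003 at -1.21 and the SPX-domain protein SPX5 at -1.21. TIP4-1 was the only one of them among the brightest 2 deciles of the probes. With median centring in place of loess 7 of these 8 no longer reached 2-fold on both arrays. Their means were then -1.44 for OsC3H37 and -1.29 for TIP4-1, where the mean held while an array fell short, and -0.97 for PCF7, -0.71 for BHLH003, -0.69 for CSLA5, -1.04 for SPX5 and -0.87 for OsC3H54. Among the higher genes OsPP2C27, UBQ3, AOS1, ACT7 and the peroxidase LOC4344277 also lost 2-fold on an array, with means of 1.53, 1.77, 1.35, 1.17 and 1.18. Without restored common factors OsC3H54 lost it too, with a mean of -1.27.

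The part of the ratios that follows the dye fell with brightness. Its robust SD was 0.94 log2 units in the dimmest decile of probes and 0.20 in the brightest. It holds dye bias besides noise, and dye bias cancels in the mean of the arrays. The part that follows irradiation had a robust SD of 0.43 in the dimmest decile, 0.52 in decile 5 and 0.23 in the brightest, so it did not fall steadily. Over all probes the arrays, once turned, correlated at r = -0.25, and in the brightest 2 deciles at r = 0.53, across probes, which are not independent replicates. The rank correlations were -0.18 and 0.31. In deciles 6, 7 and 8 r was -0.18, -0.38 and -0.26, but the rank correlation was 0.04, 0.04 and 0.14. In those brightest 4515 probes 224 were higher and 23 lower, against means of 19.6 and 1.1 when the values of an array were shuffled among probes of like brightness. In the 6772 probes of the next 3 deciles 147 were higher and 22 lower, PCF7, OsC3H37 and CIPK7 among the lower ones, against 34.8 and 19.0. Deciles 6, 7 and 8 hold 35, 89 and 68 of the 202 spots that follow the dye. Shuffling pairs the extreme values of these spots with other probes, which adds calls. The 34.8 and 19.0 are therefore not what technical error alone would give, and cannot decide whether the lower calls there stand apart from it. Over all probes the 68 lower calls were fewer than the 184.9 of shuffled values, and the 423 higher calls more than 209.2. In the brightest 2 deciles 25 probes passed 2-fold with the dye and not with irradiation, against 247 that passed with irradiation. The swapped array was turned because of these same deciles, so the sign of their r of 0.53 and the larger of these counts follow from that choice. Unturned, the counts of 25 and 247 would exchange. Over all probes 1197 passed with the dye, the 202 spots used for the numbering among them, against 491 with irradiation. Over the whole array dye-following calls therefore outnumbered irradiation calls. In the dimmer 11287 probes 52 were higher and 23 lower, fewer than the 154.8 and 164.9 of shuffled values. Shuffling removes the correlation below 0 that the arrays have there, -0.54 in the dimmest decile. Fewer calls than in shuffled values were thus likely from the start, and the same limits hold over all probes. Calls among dim probes still cannot be set apart from technical error, since 129 of 11287 unchanged dim probes were called in simulated arrays. The probes given for AOX1, CDC2-2, CSLA5, SPX5, OsC3H54, BHLH003, OsPP2C75, PBZ1 and HSP101 lie there.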

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

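The tests at 1.5-fold and 3-fold, centring, each array alone and counts per gene were planned, and the as-deposited reading, the opposite numerator and the bright-probe values were chosen after the data were seen. The counts of 423 higher and 68 lower probes were 640 and 232 by the mean of the arrays, 925 and 482 at 1.5-fold, 187 and 7 at 3-fold, 257 and 27 with median centring, 251 and 28 with scaling as well, and 224 and 23 in the brightest 2 deciles. The share higher was 65.7% at 1.5-fold, 73.4% by the mean and 90.5% with median centring, but 52.2% on the first array alone and 54.9% on the swapped array alone. With median centring in place of loess 207 of the 423 and 14 of the 68 probes were shared. Each array alone gave 1924 to 2308 higher and 1765 to 1894 lower. Read as deposited, both columns as irradiated over control, 3429 probes were higher and 1894 lower. With Cy3 over Cy5 the counts turn to 68 higher and 423 lower. Counts per gene, loess on reduced terms and a wider span left both counts within 1.5 times. The correlation of -0.25 was -0.18 by ranks, -0.37 without the 1% largest changes, 0.53 in the brightest 2 deciles and 0.67 for the columns as deposited. Pathogenesis-related, P450, heat shock and phenylpropanoid genes were each called in 1 setting only. Pathogenesis-related genes were high with median centring (0.22, percentile 99.4). Heat shock genes were high on the first array alone (0.35, percentile 99.5), but -0.017 on the swapped array. Phenylpropanoid genes were high on the swapped array alone (0.28, percentile 97.7). P450 genes were low with scaling (-0.16, percentile 2.39), but 0.23 at percentile 97.3 on the swapped array. Of the 5 lists called in the main analysis, the root list was -0.227 on the first array alone and turned to 0.038 on the swapped array alone. With probes numbered as listed the jasmonate and ethylene median was -0.030, the cell wall median 0.034 and the root median 0.064, and 0 lists were called. 0 of the 37 named genes changed sign with median centring or with loess on reduced terms. Each array alone could not turn them, since they were picked for the same sign on both, and Cy3 over Cy5 turns all of them. With median centring 12 lost their side of 2-fold, among them 7 of the 8 lower genes. No paired analysis was possible because there is 1 replicate per group and no test. Signal over background is not given, so dim probes limit what can be told, and the cause of each change was not tested.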

Other observations

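The tests in this part were chosen after the results they bear on were seen, except median centring, which was planned. Some of 14 gene families, picked by name, held further differences. Stress-associated A20/AN1 zinc-finger proteins, the family of SAP17, had 3 of 14 probes at least 2-fold higher, SAP17 at 4.05, SAP4 at 1.56 and SAP16 at 1.13, and 0 lower, but the family's median lay at percentile 88.0 and was not high. Of 12 JAZ repressor genes, which overlap the jasmonate list, the median over 14 probes was 0.67, and JAZ9 and JAZ7 stood at 1.09 and 1.02 besides the members past 2-fold on both arrays. Of 5 WRKY genes 3 were at least 2-fold higher, and of 9 NAC genes 5 and the median over 11 probes was 0.51. Among PDR-type ABC transporters ABCG44 stood at 2.48 and ABCG36, a dim probe, at 1.77, with the family's median at percentile 96.6, which is not high. The potassium transporters HAK1 and HAK27 stood at 2.10 and 1.35, while the median of 24 HAK probes was 0.02 at percentile 57.5.

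Some other families lay below 0 with no probe past 2-fold on both arrays. Beta-expansins, which loosen cell walls, had a median of -0.32 over 12 probes at percentile 0.91, with 0 past 2-fold. SWEET sugar transporters had a median of -0.26 over 12 probes at percentile 2.36, where SWEET14 stood at -1.18 and SWEET4 at 0.88. Kinesins had a median of -0.18 over 25 probes, 14 of them dim, at percentile 2.96, or 5.28 when matched on intensity, which is not low. Hexokinases had a median of -0.45 over 9 probes, 6 of them dim, at percentile 0.28, but 0.07 on the swapped array alone, so their direction depends on the array. AUX/IAA repressors, auxin response factors, MADS-box factors and homeobox factors did not stand apart, with medians of -0.08, -0.07, 0.07 and 0.05, between percentiles 16.98 and 79.6.

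More probes were higher than lower under the Cy5 over Cy3 reading, and under Cy3 over Cy5 all shares turn and the excess is of lower probes. With median centring in place of loess the counts fell from 423 higher and 68 lower to 257 and 27, of which 207 and 14 were shared, so loess bears on their size, but 90.5% of the calls were still in the same direction, so it does not account for the whole excess. A shift of all genes alike cannot be seen in these ratios, since both methods set the middle of each array to 0. Noise of dim probes would bring the share of higher calls toward balance in bright probes, and it was 90.7% in the brightest 2 deciles. That share cannot decide the question, since shuffled values there also gave mostly higher calls, with means of 19.6 higher and 1.1 lower. The 224 higher calls there were more than 19.6, but the swapped array was turned on the strength of these deciles. Over all probes the share of higher calls was 52.2% on the first array alone and 54.9% on the swapped array alone, where calls that follow the dye count too. The large excess is thus among calls made on both arrays. Handling of the irradiated extract other than the beam, such as transport or time outside the chamber, cannot be told apart from irradiation, because there was 1 extract per group.

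The columns correlated above 0 although the labels swap the dyes. If both columns were irradiated over control they would correlate above 0 among bright probes too, and there they correlated at -0.53 after normalization, the observation that led to the reading used here. A candidate explanation is that both columns are the same dye over the other, with a dye bias that follows intensity, since over 535 bright probe pairs of the same gene the part that changes sign between columns had a rank correlation of 0.28, and the part with the same sign one of 0.034. These pairs rest on the recovered probe numbering, and the first score that chose the numbering rests in turn on this reading of the columns. Cy3 as the numerator stays open, because neither label nor file names it, and 68 probes would then be higher. No biological explanation was tested.

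The annotation's probe numbers did not pair with the rows as listed. As listed, 15.8% of the spots that follow the dye on both arrays were unlisted, under the 21.0% of all probes, where control spots would be mostly unlisted. A candidate explanation is that the rows run down the columns of the grid from the opposite corner. Under that numbering the irradiation part of 535 bright probe pairs of the same gene had a rank correlation of 0.28 across pairs, against 0.033 over 557 pairs as listed. This score was not among those that chose the numbering. No biological explanation was tested.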
